A study of Homo sapiens with 3 samples.

How the data were processed

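Single-cell RNA of human retinal organoids was counted in 3 libraries, 1 per group, with the groups untreated, VEGFA-treated and NT-treated per the labels. The values are UMI counts per gene and barcode, as the authors deposited them in 10x Genomics matrix format, where a UMI is a tag that marks 1 captured RNA molecule. Cell Ranger 7.1.0, Seurat 4.3 and the GRCh38 genome were used, per the submitters' processing notes. Whether intronic reads were counted is not given in the sources used here. The extract protocol of the labels names an RNeasy Mini kit for whole organoids, although the matrices hold counts per cell. The untreated label alone names the H9 line, and the lines of the treated libraries are not given. All libraries shared 36601 features, of which 0 were named for Cas13 or a vector, so delivery could not be measured.

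The 27720 barcodes had a median of 7344.5, 14613 and 12962 UMIs in the untreated, VEGFA-treated and NT-treated libraries, the order of all sets of 3 values. Barcodes with under 500 detected genes (123, 114 and 126) and those with over 20% mitochondrially encoded UMIs (40, 22 and 58) were removed. Doublets were scored per library with Scrublet as built into scanpy. Its automatic threshold marked only 2, 6 and 3 barcodes, and the barcodes with the highest scores were removed instead, at 0.8% per 1000 barcodes (1066, 446 and 607). Kept cells numbered 25162, with a median of 3414, 4920 and 4631.5 genes and a median mitochondrial share of 3.55%, 2.93% and 4.33%. These filters, the comparisons, the marker lists, the gene lists and most alternatives were fixed before the data were examined.

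Counts were scaled to 10000 per cell and log-transformed. Cells were clustered with scanpy on 3000 variable genes without VEGFA, 30 principal components, 15 neighbours and Leiden resolution 1, all libraries together and without batch integration. Clusters were named from 19 fixed marker lists by a rule set after the clusters were seen. A marker counted when its CPM was at least 2-fold the median cluster and at least 10% of cells held it. A name needed at least 3 markers, at least 60% of the list and a margin of 10 percentage points over the second list, and no other list with more markers among the 10 top genes. Of 27 clusters 17 were named, giving 6 classes, of which 5 had at least 50 cells in every library and were compared. Unnamed clusters failed the margin (35.7%, 11.9% and 7.46% of kept cells), the minimum share (6.69%, 21.5% and 10.5%), the top genes (3.79%, 7.71% and 8.21%) or had few UMIs and no marker on top (0.252%, 0.377% and 0.189%).

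The largest part of a class lay in cluster 12 for Müller glia-like, cluster 5 for rod-like, cluster 14 for cone-like and cluster 7 for horizontal-like cells in every library. For bipolar-like cells it lay in cluster 17 in the untreated library and in cluster 11 in the treated libraries. Within the named classes, cluster 9 (rod-like, 50, 237 and 264 cells) was led by rod markers with AC093866.1 and the stress gene GADD45A. Cluster 20 (cone-like, 421, 420 and 359 cells) was led by PCAT4 and ATF5, with PURPL and CEBPB, and cluster 24 (Müller glia-like, 60, 51 and 9 cells) by FBLN2 and APOC1, with PAX2, PAX5, BST2 and SERPINA3. Cluster 24 also held 9 markers of the cycling list, a share of 0.75. Cluster 0, unnamed, had 97.2% of its cells from the untreated library, so it may reflect that library more than a cell type.

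UMIs were summed per gene, class and library and given as counts per 1000000 UMIs (CPM). With 1 library per group no test, standard error or count of significant genes was possible. Intervals are exact Poisson for UMI sums and exact binomial for shares, at 95%. Ratios are log2 ratios of CPM. A library with 0 UMIs was set to 3 UMIs and the ratio given as a bound, and no ratio was given where both libraries lay at or under that floor. Genes tested had at least 100 UMIs over the libraries in the class and at least 30 CPM in the highest. A gene set a library apart when it differed from both other libraries by at least 2-fold in the same direction. For whole-library levels the class levels were also weighted to the mean class shares of the libraries: Müller glia-like 17.5%, bipolar-like 9.82%, cone-like 28.3%, horizontal-like 9.32% and rod-like 35.04%. Cells outside these classes were left out of the weighted values. For shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out.

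For each of 23 fixed gene lists with at least 5 members measured, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 expression bins. Genes named are VEGFA, and, in the 3 classes with the most cells, the 5 highest and 5 lowest of those that set a library apart, ranked by the smaller of their absolute log2 ratios. List members named are 2 to 4 with the largest absolute ratio of VEGFA-treated to NT-treated, and markers of other cell types come from the fixed marker lists. Mitochondrially encoded genes and genes tied to sex were left out of the ranked names. The number of cells holding 90% of a gene's UMIs was counted.

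The scripts were tested on simulated data drawn from the real levels and depths. These data held counting error only, without differences between cells, clusters or cultures. In simulated rod-like cells (6659 genes) the VEGFA-treated comparison recovered 65 of 66 genes raised or lowered 4-fold, 66 of 67 at 2.5-fold and 0 of 67 at 1.5-fold, in simulated cone-like cells (6219 genes) 65 of 66 genes raised or lowered 4-fold, 66 of 67 at 2.5-fold and 0 of 67 at 1.5-fold, and in simulated Müller glia-like cells (6098 genes) 62 of 66 genes raised or lowered 4-fold, 63 of 67 at 2.5-fold and 0 of 67 at 1.5-fold. No unchanged simulated gene was called apart. Of 100 simulated unchanged lists per class, 2, 4 and 5 fell outside the central 95% of percentiles in rod-like, cone-like and Müller glia-like cells. With no true difference, 0 of 6687 rod-like, 0 of 6246 cone-like and 0 of 6086 Müller glia-like genes stood apart from untreated in both treated libraries.

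Alternatives were a mitochondrial limit of 10%, no doublet removal, median-of-ratios size factors, every cell weighted the same, genes centred within library, Leiden resolutions 0.5 and 2, no CPM minimum with at least 20 UMIs, 5 CPM added, a 1.5-fold threshold and other thinning depths, with further alternatives chosen after seeing the data. These were a naming rule with a minimum share of 50% and no margin, analyses without cluster 0, without cluster 15 or without clusters 9, 20 and 24, VEGFA with the clusters of each class at their mean share of the class UMIs over the libraries, and genes held by at least 5% of cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.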

Results

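The series holds 3 droplet libraries of human retinal organoids, which are stem cell cultures that form layered retinal tissue. 1 library was labelled untreated, with the label naming H9, a human embryonic stem cell line. The other libraries were labelled VEGFA-treated and NT-treated, and the sources used here do not spell out the second abbreviation. The series concerns Cas13bt3, a small RNA-guided enzyme that cuts RNA, directed at the mRNA of VEGFA. VEGFA encodes a growth factor for blood vessels. The files held 11544 barcodes with 137299444 UMIs in the untreated library, 7467 barcodes with 157670545 UMIs in the VEGFA-treated library, and 8709 barcodes with 157559151 UMIs in the NT-treated library. After filtering, 10329, 6901 and 7932 cells were kept, with a median of 7377, 14193 and 12263 UMIs per cell. Sets of 3 values are given in the order untreated, VEGFA-treated and NT-treated. Each group had 1 library, so no difference between libraries has a replicate check, and every interval covers counting error only.

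Rod-like, cone-like, Müller glia-like, bipolar-like and horizontal-like cells were found in all 3 libraries. Rod-like cells made up 18.4% (17.7 to 19.2%) of the kept cells of the untreated library, 13.5% (12.7 to 14.3%) of the VEGFA-treated library and 34.8% (33.7 to 35.8%) of the NT-treated library, with exact binomial 95% intervals in parentheses. Cone-like cells made up 14.4%, 16.7% and 21.4%, or 9.11%, 11.7% and 15.9% without doublet removal. Müller glia-like cells, the main support cells of the retina, made up 10.1%, 13.7% (12.9 to 14.5%) and 7.30% (6.74 to 7.89%). Horizontal-like cells made up 2.98%, 8.52% and 5.70%, and bipolar-like cells 6.95%, 5.98% and 4.46%. Retinal pigment epithelium-like cells numbered 79, 6 and 0, and the count of 0 allows a share of up to 0.0465%. Cells of unnamed clusters made up 46.4%, 41.5% and 26.3%. Cluster 0, unnamed because it held markers of Müller glia and of rods at a similar share, had 3285 cells of the untreated library, 50 of the VEGFA-treated library and 46 of the NT-treated library. With a looser naming rule chosen after seeing the data, that cluster joined the Müller glia-like class, which then made up 41.9% of the untreated library.

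**Figure D1:**
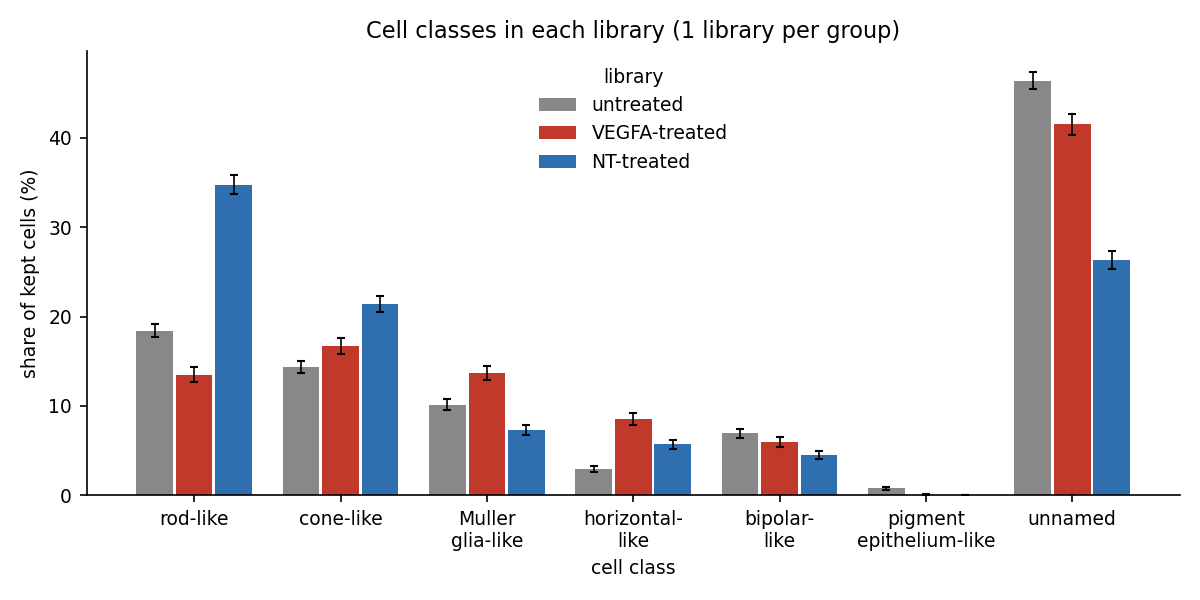
Share of kept cells (%, y axis) in each cell class (x axis) for each library, with exact binomial 95% intervals as error bars (counting error only). Rod-like cells made up 34.8% of the NT-treated library and 13.5% of the VEGFA-treated library, and cells of unnamed clusters 46.4% of the untreated library.

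The first comparison asked how much VEGFA mRNA each library held. VEGFA (ENSG00000112715; GRCh38 chromosome 6, 43770184 to 43786487, plus strand) stood at 89.1 CPM (87.4 to 90.8) over all kept cells of the untreated library, 33.5 CPM (32.6 to 34.5) in the VEGFA-treated library and 35.7 CPM (34.7 to 36.7) in the NT-treated library. The log2 ratio was -1.41 (95% interval -1.46 to -1.36) for VEGFA-treated over untreated and -1.32 (-1.37 to -1.27) for NT-treated over untreated. Both treated libraries thus held less VEGFA than the untreated library, and the ratio of VEGFA-treated to NT-treated was -0.09 (-0.15 to -0.03). Averaged with every cell at the same weight, that last ratio was 0.16, the opposite direction. With the libraries weighted to 1 common class composition, VEGFA stood at 84.9, 36.4 and 41.8 CPM, and the ratios were -0.20 (-0.28 to -0.11) for VEGFA-treated over NT-treated, -1.22 (-1.29 to -1.15) for VEGFA-treated over untreated and -1.02 (-1.09 to -0.96) for NT-treated over untreated.

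VEGFA was highest in horizontal-like and Müller glia-like cells of the untreated library, and within both classes it was lower in the VEGFA-treated than in the NT-treated library. In Müller glia-like cells it stood at 194, 73.5 and 102 CPM, a log2 ratio of -0.48 (-0.60 to -0.35) for VEGFA-treated over NT-treated and -0.92 (-1.03 to -0.81) for NT-treated over untreated. In horizontal-like cells, the interneurons that contact photoreceptors, it stood at 273, 45.9 and 77.6 CPM, with ratios of -0.76 (-0.93 to -0.59) and -1.81 (-1.94 to -1.68) in the same order. Cone-like cells had 34.2, 21.2 and 25.6 CPM and a ratio of VEGFA-treated to NT-treated of -0.27 (-0.42 to -0.12). Bipolar-like cells had 35.1, 23.4 and 21.7 CPM, and their ratio of 0.11 (-0.36 to 0.58) was not distinguishable from no difference at this depth, and was -0.16 with every cell weighted the same. In rod-like cells VEGFA was higher in the VEGFA-treated than in the NT-treated library, at 35.3, 31.3 and 20.7 CPM and a ratio of 0.59 (0.38 to 0.80). Rod-like cells lay in different clusters by library: cluster 6, with a VEGFA level of 51.7 CPM, held 34.8%, 17.4% and 8.99% of them and cluster 5, at 17.8 CPM, 39.4%, 33.1% and 51.5%. With the clusters of the class at a common share, an alternative chosen after seeing the data, the rod-like ratio was 0.28 (0.04 to 0.51). The rod-like ratio of VEGFA-treated to untreated was -0.17 (-0.39 to 0.04), with an interval that holds 0. The Müller glia-like ratio of VEGFA-treated to NT-treated was -1.0 with the mitochondrial limit at 10%, -0.92 with finer clusters, -0.78 without clusters 9, 20 and 24, -0.69 with clusters at a common share, where that of NT-treated to untreated was -0.59, and -0.28 with every cell weighted the same. The cone-like ratio was -0.45 with finer clusters and -0.49 without those clusters, whose 10 top genes include stress genes or genes of other lineages and which were singled out after seeing the data. UMI counts per gene do not separate cut from intact transcripts, and the position in VEGFA that the guide matches is not given in the sources used here.

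**Figure D2:**
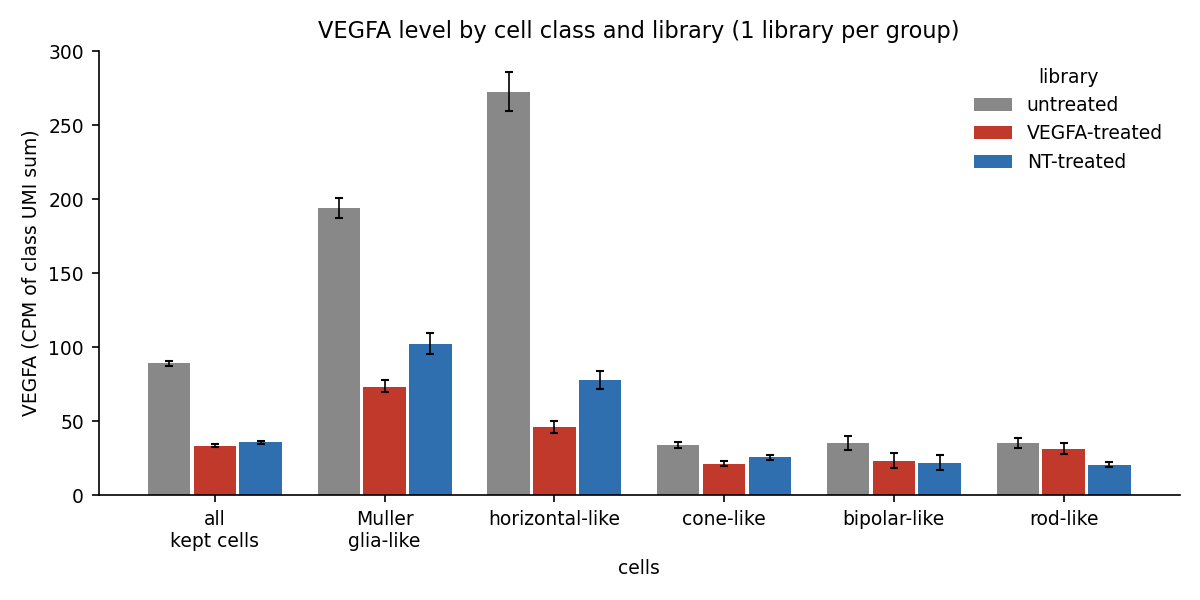
VEGFA level (CPM, y axis) in all kept cells and in each class (x axis) for each library, with exact Poisson 95% intervals as error bars (counting error only). Horizontal-like cells stood at 273, 45.9 and 77.6 CPM in the untreated, VEGFA-treated and NT-treated libraries, and rod-like cells at 35.3, 31.3 and 20.7 CPM.

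The share of cells with a VEGFA UMI was compared after every cell was thinned to 1000 UMIs, which left out 577, 282 and 299 shallower cells. The thinned share was 7.42% (6.91 to 7.96%) in the untreated library, 3.55% (3.12 to 4.02%) in the VEGFA-treated library and 3.07% (2.69 to 3.48%) in the NT-treated library, against 34.3%, 31.5% and 28.5% without thinning. In Müller glia-like cells it was 12.7%, 6.22% and 8.03% (unthinned 59.9%, 47.99% and 49.7%), and in horizontal-like cells 22.1%, 4.27% and 4.93% (unthinned 73.1%, 36.6% and 46.7%). The lowest shares of any class were 3.17% in cone-like cells of the untreated library (median 18863 UMIs), 2.70% in bipolar-like cells of the VEGFA-treated library (median 7940) and 2.02% in rod-like cells of the NT-treated library (median 6406). Free RNA was not measured, and these shares come from a different class in each library, so they do not give its level. Müller glia-like cells had medians of 14561, 16758 and 13518 UMIs. The all-cell thinned share was higher in the VEGFA-treated than in the NT-treated library while its CPM was lower, so no order between those libraries is read from the share.

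The next comparison asked which genes set the VEGFA-treated library apart from both other libraries, that is, by at least 2-fold in the same direction. In Müller glia-like cells 66 of 6570 genes were higher and 7 lower in the VEGFA-treated library, led by S100A9, PSCA, KRT13, S100A8 and LYPD2, genes typical of surface epithelia. S100A9 stood at 578 CPM with 0 UMIs in both other libraries, at least 1654-fold higher than in the NT-treated library. KRT13, a keratin of stratified epithelium, stood at 286 CPM (at least 819-fold), S100A8 at 216 CPM (at least 618-fold) and LYPD2 at 175 CPM (at least 500.2-fold). PSCA stood at 0.235, 329 and 0.116 CPM, with 1 UMI in the NT-treated library and a log2 ratio of 11.46 (8.99 to 16.77). These genes came from few cells: 8 of the 944 Müller glia-like cells of that library held 90% of the S100A9 UMIs, 6 those of PSCA, 10 those of KRT13, 5 those of S100A8 and 4 those of LYPD2. Genes lower in the VEGFA-treated library were NECTIN3-AS1 at 204, 14.5 and 211 CPM, NDUFA4L2 at 225, 84.7 and 232 CPM, a mitochondrial protein induced by low oxygen, LINC01619 at 69.5, 26.3 and 63.1 CPM and PDE10A at 291, 113 and 268 CPM, which breaks down cyclic nucleotides. MGP, an inhibitor of calcification, was also lower, at 319.9, 0.171 and 6.64 CPM, with 3 UMIs in the VEGFA-treated library and a log2 ratio to the NT-treated library of -5.28 (-7.60 to -3.66). For every gene named in the text with at least 30 UMIs in each library, the bounds of a log2 ratio lie at most 0.59 from the middle of its interval. By the same rule 8 genes were higher and 53 lower in the NT-treated library, a total of 61 that ranged from 15 to 953 over the alternatives. The 73 genes apart in the VEGFA-treated library became 14 with the mitochondrial limit at 10% (5 higher and 9 lower) and 29 with finer clusters (7 higher and 22 lower). The excess of higher genes thus did not hold under either alternative.

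In rod-like cells the VEGFA-treated library had 26 of 7011 genes higher and 5 lower than both other libraries. The highest ratios were those of GPNMB at 2.69, 38.95 and 7.75 CPM, a lysosomal membrane protein, GADD45B at 9.75, 34.8 and 6.58 CPM, GDF15 at 2.47, 35.4 and 11.1 CPM, a secreted stress factor, PHGDH at 15.5, 43.7 and 16.7 CPM, the entry enzyme of serine synthesis, and GADD45A at 169, 714 and 286 CPM, a growth arrest gene. The log2 ratio of VEGFA-treated to NT-treated was 2.33 (2.07 to 2.59) for GPNMB and 1.32 (1.27 to 1.37) for GADD45A. Lower genes were KIAA1217 at 179.9, 67.2 and 145 CPM and PCDH15 at 302, 150.3 and 318 CPM, a cadherin of photoreceptor and hair cells, and the other 3 were mitochondrially encoded. GADD45A was among the genes leading cluster 9, which held 237 of the 930 rod-like cells of the VEGFA-treated library, 264 of 2758 in the NT-treated library and 50 of 1901 in the untreated library. Without clusters 9, 20 and 24, 6 rod-like genes set the VEGFA-treated library apart, 1 of them among the 31. Coarser clusters gave 8 and genes centred within each library 60. The NT-treated library had 2 higher and 10 lower, or 0 and 9 with every cell weighted the same.

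Cone-like cells had fewer such genes, with 2 of 6542 higher and 7 lower in the VEGFA-treated library, and 1 higher and 10 lower in the NT-treated library. Higher in the VEGFA-treated library were AL627171.2 at 38.7, 91.4 and 40.7 CPM and CLTB at 258, 589 and 288 CPM, a light chain of clathrin, with a log2 ratio to the NT-treated library of 1.03 (1.0 to 1.07). Lower were POU2AF1, a transcriptional coactivator, at 39.9, 0.698 and 15.5 CPM and a ratio of -4.48 (-5.22 to -3.82), LINC01440 at 57.6, 11.9 and 37.5 CPM, HK2 at 42, 9.55 and 28.4 CPM, a hexokinase of glycolysis, AL392086.3 at 34.8, 12.2 and 27.5 CPM and DIAPH2-AS1 at 81.6, 31.02 and 66.7 CPM. With 5 CPM added to every value, 5 cone-like genes stood apart in place of 9. NECTIN3-AS1 and DIAPH2-AS1 are antisense genes, and strand use in the counting is not given in the sources used here.

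Heat shock genes, which encode protein chaperones, were higher in the VEGFA-treated than in the NT-treated library in every class compared. The median log2 ratio of the 11 members measured after weighting was 0.71, at percentile 100 among 10000 random lists matched on expression, a description of these libraries. Class medians were 0.70 in Müller glia-like, 1.08 in rod-like, 0.95 in cone-like, 0.98 in bipolar-like and 0.78 in horizontal-like cells. In Müller glia-like cells 5 of 12 members were at least 2-fold higher and 0 lower, with HSPB1 at 246, 335 and 133 CPM, HSPA1B at 494, 661 and 278 CPM, HSPH1 at 515, 435 and 204 CPM and HSPA1A at 1046, 1087 and 526 CPM. Rod-like cells had HSPB1 at 34.4, 32.01 and 5.49 CPM and HSPA1A at 868, 925 and 208 CPM, and horizontal-like cells HSPA1B at 101, 159 and 16.1 CPM and HSPA1A at 316, 349 and 48.2 CPM. HSPA1A and HSPA1B are nearly identical, so their separate values are uncertain. The VEGFA-treated and untreated libraries were closer, with a weighted median of 0.28 (percentile 94.8), and the NT-treated library lay below the untreated library at -0.44 (percentile 0).

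Targets of p53, a regulator of the DNA damage response, were also higher in the VEGFA-treated than in the NT-treated library, with a weighted median of 0.54 over 18 members (percentile 100). The ratio was largest in rod-like cells, at 0.96, where 7 of 16 members were at least 2-fold higher and 0 lower. There TRIAP1 stood at 38.5, 158 and 67.5 CPM and MDM2, the ubiquitin ligase that degrades p53, at 66.01, 199 and 93.98 CPM, next to GDF15 and GADD45A. Without clusters 9, 20 and 24 the rod-like median was 0.37, no longer the largest of the classes, and the weighted median 0.25. Genes of the unfolded protein and integrated stress response had a rod-like median of 0.69, with 4 of 14 members at least 2-fold higher and 0 lower, among them ATF3 at 14.3, 39.4 and 17.6 CPM and DDIT3 at 245, 681 and 331 CPM, both stress-induced transcription factors. Interferon-stimulated genes, the antiviral response set, had a weighted median of 0.40 over 14 members (percentile 100). By class that median was 0.58 in Müller glia-like, 0.38 in rod-like, 0.29 in cone-like, 0.58 in bipolar-like and -0.62 in horizontal-like cells. Horizontal-like cells thus went the other way, with 3 of 9 members at least 2-fold lower in the VEGFA-treated library, namely ISG15 at 6.29, 24.5 and 73.3 CPM, IFI6 at 10.2, 122 and 331 CPM and B2M at 29.3, 60.8 and 139 CPM. With the mitochondrial limit at 10% the interferon median was 0.07 in Müller glia-like cells and 0.15 after weighting.

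Mitochondrially encoded and phototransduction genes were lower in the VEGFA-treated than in the NT-treated library. The 13 mitochondrially encoded genes had a weighted median of -0.60 (percentile 0), and class medians of -0.58 in Müller glia-like, -0.93 in rod-like, -0.46 in cone-like, -0.56 in bipolar-like and -0.09 in horizontal-like cells. MT-ND6 stood at 127, 60.8 and 159 CPM in rod-like cells and MT-CO3 at 4155, 1986 and 4485 CPM. Cells with under 0.5% of UMIs from these genes made up 11.8%, 24.5% and 14.3% of kept cells. The median mitochondrial share was 1.85% in rod-like cluster 9 against 4.58% in cluster 5, and 0.19% in cone-like cluster 20 against 5.47% in cluster 14. Cluster 9 held 25.5% of VEGFA-treated and 9.57% of NT-treated rod-like cells, and cluster 20 held 36.4% and 21.1% of cone-like cells. The class medians thus need not mean lower expression within a cluster. Phototransduction genes, which turn light into a nerve signal, had a weighted median of -0.31 over 26 members (percentile 0), and -0.33 in rod-like cells, where 0 of 22 were at least 2-fold higher and 0 lower, or -0.09 and -0.08 without clusters 9, 20 and 24. PDE6G, a phosphodiesterase subunit, stood at 962, 593 and 943 CPM there. Cone opsins in cone-like cells were OPN1LW at 65.4, 30.99 and 113 CPM, OPN1SW at 322, 363 and 150.1 CPM and OPN1MW at 370.3, 321 and 773 CPM, where OPN1LW and OPN1MW are near-identical copies with uncertain separate values. Hypoxia targets had a weighted median of -0.10 (percentile 26.97) and genes of RNA decay and RNA sensing one of -0.04 over 6 members (percentile 52.7).

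The last comparison set both treated libraries against the untreated one. Interferon-stimulated genes were higher in both treated libraries in all 5 classes compared, with the highest median in Müller glia-like cells for VEGFA-treated and in horizontal-like cells for NT-treated. In the former class 20 of 23 members were at least 2-fold higher in the VEGFA-treated library and 16 in the NT-treated library, with none lower, and medians of 2.61 and 1.46. IFI6 stood at 51.8, 912 and 514 CPM, ISG15, a ubiquitin-like modifier, at 28.5, 475 and 297 CPM, IFIT3 at 4.47, 75.4 and 45.8 CPM, OAS1, a sensor of double-stranded RNA, at 2.65, 53.6 and 30.9 CPM and MX1 at 1.88, 39.6 and 19.7 CPM. The log2 ratio of IFI6 to untreated was 4.14 (4.04 to 4.24) in the VEGFA-treated and 3.31 (3.21 to 3.42) in the NT-treated library. Of the 944 VEGFA-treated and 579 NT-treated cells of the class, 245 and 163 held 90% of the IFI6 UMIs. For ISG15 these were 141 and 74 cells, for OAS1 127 and 74, for MX1 100 and 35 and for IFIT3 83 and 28. Members that differed most between the treated libraries were IFI27 at 6.82, 182 and 26.8 CPM, IFI44 at 5.53, 33.7 and 11.6 CPM, BST2 at 18.3, 195 and 85 CPM and B2M at 385, 1635 and 742 CPM. With finer clusters the IFI27 ratio of NT-treated to untreated was -0.13, and with the mitochondrial limit at 10% the median of the list for VEGFA-treated over untreated was 1.19. Class medians of the list for VEGFA-treated over untreated were 2.61 in Müller glia-like, 0.90 in rod-like, 0.71 in cone-like, 1.78 in bipolar-like and 1.01 in horizontal-like cells, and for NT-treated over untreated 1.46 in Müller glia-like, 0.56 in rod-like, 0.52 in cone-like, 0.86 in bipolar-like and 1.74 in horizontal-like cells. For NT-treated over untreated the horizontal-like median was 0.86 with the mitochondrial limit at 10% and the rod-like median 0.16 without clusters 9, 20 and 24. After thinning, the share of Müller glia-like cells with an IFI6 UMI was 4.70%, 30.3% and 22.4% (unthinned 44.5%, 76.7% and 69.6%), against 0.949%, 1.92% and 2.52% in rod-like cells, whose median depths were 6929, 6880.5 and 6406 UMIs.

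Targets of p53 were higher than in the untreated library too, with weighted medians of 1.39 for VEGFA-treated and 0.67 for NT-treated (percentile 100 for each). Of 18 members measured in Müller glia-like cells 12 were at least 2-fold higher in each treated library and none lower, among them GDF15 at 21.3, 98.5 and 45.9 CPM, GADD45A at 53.1, 252 and 151 CPM and FDXR at 11.5, 81.3 and 50.6 CPM, a mitochondrial reductase, while BTG2 stood at 163, 201 and 346 CPM. Cycling markers in the same class had medians of -1.81 and -2.74 (percentile 0 for each), with MKI67 at 41.4, 10.96 and 4.54 CPM and 90% of its UMIs in 28, 11 and 5 cells. Cluster 24, which held 9 markers of the cycling list, had 60, 51 and 9 cells of the class, and its part in these medians was not tested. TTR, a pigment epithelium marker, stood at 7.53, 56.4 and 29.3 CPM in the class. In rod-like cells 12 of 16 were at least 2-fold higher in the VEGFA-treated and 5 in the NT-treated library, with medians of 1.71 and 0.75, or 0.49 and 0.04 with coarser clusters. Markers of other cell types were higher in those rod-like cells too, with TTR at 48.5, 280.3 and 186 CPM and the cone genes PDE6H at 129.8, 315 and 208 CPM and OPN1SW at 17.6, 44.03 and 35.97 CPM. Retinal pigment epithelium-like cells numbered 79, 6 and 0, so TTR in rod-like and Müller glia-like cells did not follow their number. In horizontal-like cells the medians were 0.47 and 0.34, and -0.07 and -0.08 with the mitochondrial limit at 10%.

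Hypoxia (HIF) targets, a list without VEGFA, were lower in both treated libraries, with weighted medians of -0.51 for VEGFA-treated and -0.48 for NT-treated over untreated (percentile 0 for each). The lowest class medians were those of horizontal-like cells, at -1.11 and -1.19, where 10 of 16 members were at least 2-fold lower in each treated library and none higher. Examples were DDIT4 at 61.9, 28.2 and 15.6 CPM, PDK1 at 55.96, 14.3 and 20.7 CPM, which limits the flow of pyruvate into mitochondria, and EGLN3, an oxygen-sensing hydroxylase, at 36.8, 7.04 and 5.37 CPM. Glycolysis genes in horizontal-like cells had medians of -0.60 and -0.62, with 6 of 16 members at least 2-fold lower in each, including HK2 at 31.6, 4.84 and 7.58 CPM and SLC16A3 at 42.6, 12.2 and 17.2 CPM, while LDHA stood at 162, 107 and 70.9 CPM and LDHB at 152, 216 and 150.3 CPM. Without doublet removal those glycolysis medians were -0.09 and -0.24. Beside these lists and VEGFA, Müller glia markers were lower in the treated libraries in horizontal-like cells: APOE at 88.7, 13.98 and 13.9 CPM and WIF1 at 30.5, 1.74 and 2.33 CPM, with ratios of WIF1 to untreated of -4.13 (-4.90 to -3.45) and -3.71 (-4.45 to -3.04). In the untreated library 17 horizontal-like cells held 90% of the APOE UMIs and 8 those of WIF1. Müller glia-like medians of the hypoxia list were -0.68 and -0.48, with 6 and 3 of 18 members at least 2-fold lower. ANGPTL4 at 30.1, 13.8 and 8.27 CPM was so in both treated libraries, PFKFB4 at 30.1, 11.6 and 18.98 CPM and EGLN3 at 54.1, 19.4 and 29.6 CPM in the VEGFA-treated library, and ANKRD37 stood at 49.8, 60.9 and 37.96 CPM. The median of all 6570 genes tested in Müller glia-like cells was -0.11 for VEGFA-treated over untreated.

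**Figure D3:**
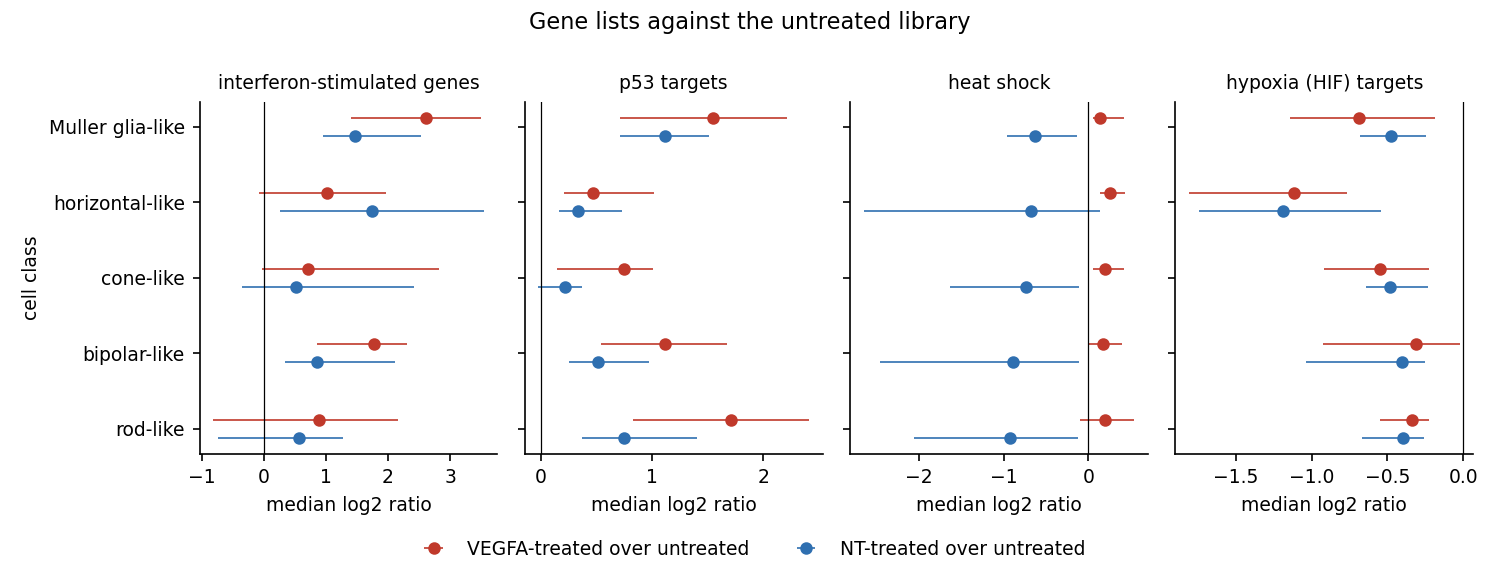
Median log2 ratio to the untreated library (x axis) of 4 gene lists in each class (y axis), with lines for the exact order-statistic 95% interval of the median over list members, which is not an error between libraries. Interferon-stimulated genes in Müller glia-like cells stood at 2.61 and 1.46, and hypoxia targets in horizontal-like cells at -1.11 and -1.19, for VEGFA-treated and NT-treated over untreated.

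Genes at least 2-fold apart from the untreated library in both treated libraries numbered 135 of 6570 in Müller glia-like cells, 38 of 7011 in rod-like, 12 of 6542 in cone-like, 58 of 6855 in bipolar-like and 84 of 6906 in horizontal-like cells. With genes centred within each library the horizontal-like count was 52, and over the alternatives it ranged from 49 to 1093. Of the Müller glia-like genes 72 were lower in both treated libraries, where lists of 133 and 143 genes drawn independently would share 2.89, and 63 were higher in both, against 2.27 from lists of 166 and 90. Simulated libraries with no true difference gave 0 such genes in Müller glia-like, rod-like and cone-like cells. They held counting error only, so they cannot show what differences between cells, clusters or cultures give. Part or all of the excess may come from the untreated library, which both comparisons share. By the same rule 73 genes set the VEGFA-treated and 61 the NT-treated library apart in Müller glia-like cells, beside the 135 of the untreated library. Lower in both treated libraries were COL3A1, a collagen, at 48.4, 0.571 and 0 CPM, MGP at 319.9, 0.171 and 6.64 CPM, DLK1 at 144, 12.8 and 12.6 CPM, a Notch pathway ligand, PAX5 at 52.4, 5.20 and 4.08 CPM, a transcription factor, and COL1A1 at 118, 14.8 and 4.89 CPM. COL3A1 had a log2 ratio of VEGFA-treated to untreated of -6.40 (-7.47 to -5.52) and, with 0 UMIs, at most 0.00722 of the untreated level in the NT-treated library, and MGP had ratios of -10.87 (-13.15 to -9.32) and -5.59 (-5.99 to -5.22) for VEGFA-treated and NT-treated. In the untreated library 5 of 1047 cells held 90% of the COL3A1 UMIs, 5 those of MGP and 6 those of COL1A1, genes of connective tissue, while 26 held those of DLK1 and 28 those of PAX5. Without clusters 9, 20 and 24, 49 of the 72 lower genes remained among 60. With the mitochondrial limit at 10% the ratios to untreated were 2.09 (VEGFA-treated) and 0.10 (NT-treated) for COL1A1 and 0.39 (NT-treated) for MGP, and with finer clusters 1.36 (VEGFA-treated) for COL1A1.

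**Figure D4:**
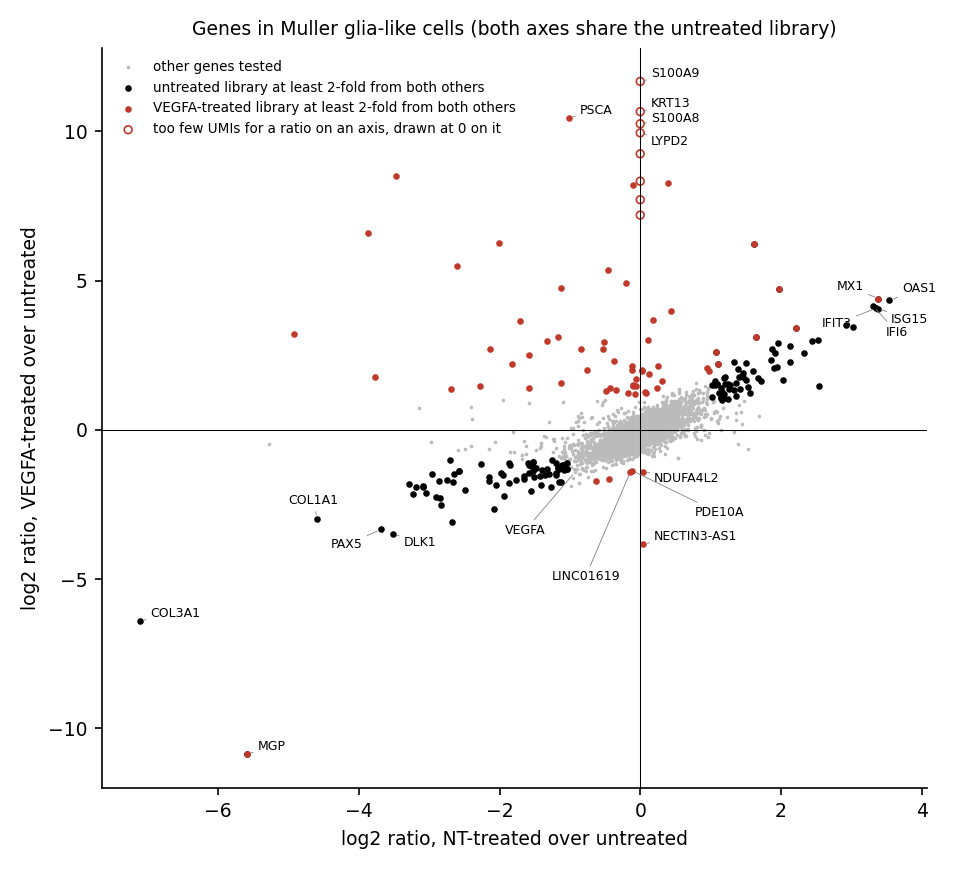
Log2 ratio to the untreated library of each gene tested in Müller glia-like cells, NT-treated on the x axis and VEGFA-treated on the y axis, with a library at 0 UMIs set to 3 UMIs and a gene that meets both rules in the colour of the VEGFA-treated library. IFI6 stood at 3.31 and 4.14, and open circles such as S100A9 had too few UMIs for a ratio on the x axis.

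In rod-like cells 38 genes set the untreated library apart, 31 the VEGFA-treated and 12 the NT-treated library. Of the 38, 10 were lower and 28 higher in both treated libraries than in the untreated one. Independent lists would share 0.193 and 0.715, but the lists compared share the untreated library, so that yardstick is too low. Lower were TENM3 at 50.8, 15.1 and 5.17 CPM, SYTL4 at 31.4, 9.63 and 10.9 CPM, CNTNAP4 at 32.02, 9.12 and 11.2 CPM, AC093898.1 at 43.7, 14.5 and 17.6 CPM and PCDH9 at 208, 86.6 and 92.2 CPM, where TENM3, CNTNAP4 and PCDH9 encode cell surface proteins of neurons. Higher were HIST2H2AA4 at 2.47, 30.3 and 23.01 CPM, a histone gene with a near-identical copy, PPP1R27 at 3.06, 36.6 and 16.7 CPM, AC093866.1 at 6.04, 52.4 and 32.6 CPM, GDF15 at 2.47, 35.4 and 11.1 CPM and PHLDA3 at 11.1, 87.8 and 44.6 CPM, a p53 target. With every cell weighted the same the counts were 16 higher and 3 lower. Without clusters 9, 20 and 24, 10 genes stood apart, 6 lower and 4 higher in both treated libraries, and 7 of them were among the 38, 6 of these lower. Coarser clusters gave 5 lower and 3 higher, so the excess of higher genes did not hold under either alternative. Without those 3 clusters the ratios to untreated were -0.03 (VEGFA-treated) and -0.13 (NT-treated) for PPP1R27 and -1.29 (NT-treated) for GDF15.

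In cone-like cells 12 genes set the untreated library apart, close to the 9 of the VEGFA-treated and 11 of the NT-treated library. Of the 12, 7 were lower and 5 higher in both treated libraries than in the untreated one. Independent lists would share 0.108 and 0.0440, but the lists compared share the untreated library, so that yardstick is too low. Lower were ZPBP at 54.7, 20.05 and 20.4 CPM, NRXN3 at 146, 54.6 and 40.2 CPM, a synaptic adhesion protein, POU2AF1 at 39.9, 0.698 and 15.5 CPM, FGF13 at 48.9, 21.2 and 16.7 CPM and KCNQ1OT1 at 229.8, 92.8 and 109 CPM. Higher were IFI6 at 19.8, 140.1 and 106 CPM, HIST2H2AA4 at 5.12, 32.5 and 23.7 CPM, FKBP2 at 22.4, 71.1 and 72.8 CPM, a prolyl isomerase of the endoplasmic reticulum, CDCA3 at 11, 35.7 and 28.3 CPM and SREBF2-AS1 at 19.3, 42.7 and 45.6 CPM. IFI6 had log2 ratios of 2.82 (2.70 to 2.95) and 2.42 (2.30 to 2.55) to untreated. Cluster 15 held 253 of the 1483 cone-like cells of the untreated library, 64 of 1155 in the VEGFA-treated and 9 of 1700 in the NT-treated library. Without it 10 genes stood apart, 7 of them among the 12 and 2 of these lower, and the ratios of VEGFA-treated to untreated were 0.20 for NRXN3 and -0.09 for FGF13. With size factors in place of total UMIs the counts were 6 higher and 5 lower. KCNQ1OT1 and SREBF2-AS1 are transcribed antisense to other genes.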

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

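All 3 tests of the lower VEGFA in both treated libraries, the rod-like VEGFA ratio read against a knockdown in every class, the test of a shift between rod-like clusters, the Müller glia RNA share needed for the VEGFA difference in rod-like cells and the interferon test of what both treated libraries received were chosen only after the result was seen. Values that went opposite ways in different classes were singled out: the VEGFA log2 ratio of VEGFA-treated to NT-treated was 0.59 in rod-like and -0.76 in horizontal-like cells, and the median of interferon-stimulated genes 0.58 in bipolar-like and -0.62 in horizontal-like cells. With 1 library per group, the difference was not tested for either.

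VEGFA was lower in both treated libraries than in the untreated library. Class composition among the 5 compared classes is argued against as the whole cause. After weighting to their common shares the ratio of NT-treated to untreated stayed at -1.02. Cells of unnamed clusters were outside that weighting. Over them the ratio was -1.38 (-1.46 to -1.29), with shifts between those clusters not weighed. Whether free RNA played a part was not decided. The cone-like level of the untreated library was 34.2 CPM against 194 CPM in Müller glia-like cells, so subtracting it could change little. After that step the Müller glia-like ratio of NT-treated to untreated was -1.06 (-1.21 to -0.92). Free RNA at the cone-like level thus does not give the whole difference, and a higher level was not tested. Lower expression of hypoxia targets went along with the lower VEGFA: the median of that list, which lacks VEGFA, lay below percentile 2.5 of random lists for both treated libraries in 5 of 5 classes. A hypothesis is that the untreated culture had less oxygen or nutrient supply, a difference between cultures that 1 library per group cannot separate from treatment, and a second untreated culture would test it.

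VEGFA was lower in the VEGFA-treated than in the NT-treated library in Müller glia-like, horizontal-like and cone-like cells and higher in rod-like cells. A knockdown of VEGFA mRNA stays open in every class, because the rod-like ratio of 0.59 is part of the pattern itself and no feature marks cells that took up the enzyme. The rod-like share of cells with a VEGFA UMI in the NT-treated library (2.02%) was the lowest of any class there. Free RNA was not measured, so that share does not show that the rod-like level is free RNA. A stressed cluster is argued against as the cause of the rod-like value, which was 0.77 (0.47 to 1.07) without cluster 9, but a shift between clusters of the class stays open, since the ratio was 0.28 (0.04 to 0.51) with clusters at a common share. Free RNA from Müller glia-like cells stays open as a small part of the cause at most. TTYH1, CLU and TF, 3 Müller glia markers, had a median ratio of 0.57 in rod-like cells against 0.59 for VEGFA. These 3 markers are too few to decide, and their ratio does not show how much VEGFA came with them. As the cause of the whole difference, or of most of it, such free RNA is argued against. The added Müller glia RNA came to 0.387% (range 0.0385 to 1.03% over 13 markers) where 14.3% is needed.

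Interferon-stimulated genes were higher in both treated libraries than in the untreated library. Free RNA from 1 source is argued against as the cause in all classes together. The ratio of IFI6 to ISG15 UMIs differed 6.83-fold between the highest and lowest class in 1 treated library and 7-fold in the other. In the VEGFA-treated library it was 13.1 in cone-like and 1.92 in Müller glia-like cells. For single classes such free RNA stays open. In the NT-treated library the ratio was 1.73 in both bipolar-like and Müller glia-like cells. Whether a few cells carried the genes stays open, since the thinned share of Müller glia-like cells with an IFI6 UMI was 22.4% in the NT-treated and 30.3% in the VEGFA-treated library, and the bounds set in advance were under 10% or over 30% in both. Genes differed in this: of 944 VEGFA-treated Müller glia-like cells 245 held 90% of the IFI6 UMIs and 83 those of IFIT3. Of 579 NT-treated cells these were 163 and 28. A response to what both treated libraries received cannot be told apart from a difference between cultures, because the weighted median of 0.93 for NT-treated over untreated rests on 1 untreated library.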

How the results depend on the processing

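The analyses without clusters 9, 20 and 24, without cluster 0, without cluster 15, with the clusters of each class at a common share, with the looser naming rule and with genes held by at least 5% of cells were chosen after the result was seen. Over 20 alternatives, 184 VEGFA ratios stayed within their counting interval, 46 moved beyond it and 1 that was set apart from 0 turned to the opposite sign. Of named gene ratios 1313 stayed, 636 moved and 10 set apart from 0 turned, and of list medians 1778 stayed, 40 moved and 2 set apart from random lists turned. Values not set apart in the main analysis also crossed 0 and are counted as stayed or moved, so that opposite signs number 2 for VEGFA, 16 for named genes and 53 for list medians in all. Among them are the bipolar-like VEGFA ratio of VEGFA-treated over NT-treated (0.11, and -0.16 with every cell weighted the same) and the weighted outer segment median of VEGFA-treated over untreated (-0.20, and 0.02 without clusters 9, 20 and 24). Counts of genes stayed within 1.5-fold 168 times and moved 57 times, class shares stayed 87 times and moved 51 times, and shares of cells with a UMI stayed 50 times and moved 40 times. Depth limits single genes most where a library holds few UMIs in a class. Ratios below are log2 and genes apart are counted per library.

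With the mitochondrial limit at 10%, the VEGFA ratio of VEGFA-treated over NT-treated was -0.32 (weighted), -1.0 (Müller glia-like) and -0.58 (horizontal-like), and that of VEGFA-treated over untreated was -1.30 (weighted), -1.57 (Müller glia-like) and -2.15 (horizontal-like). At that 10% limit, that of NT-treated over untreated was -0.57 (Müller glia-like) and -1.57 (horizontal-like), and genes apart were VEGFA-treated 14 (Müller glia-like). At that 10% limit, class shares were 7.51% Müller glia-like (untreated), 11.2% Müller glia-like (VEGFA-treated), 5.22% Müller glia-like (NT-treated) and 13.5% cone-like (untreated), and the p53 target median VEGFA-treated over untreated was -0.07 (horizontal-like). At that 10% limit, the p53 target median NT-treated over untreated was -0.08 (horizontal-like), and gene ratios of opposite sign were 2.09 (COL1A1, VEGFA-treated over untreated), 0.10 (COL1A1, NT-treated over untreated) and 0.39 (MGP, NT-treated over untreated) in Müller glia-like cells, and the cause was not tested. Without doublet removal, the VEGFA ratio of VEGFA-treated over untreated was -1.32 (all cells), -1.36 (weighted) and -1.54 (Müller glia-like), and that of NT-treated over untreated was -1.24 (all cells), -1.19 (weighted) and -1.10 (Müller glia-like). Without that removal step, class shares were 15.3% Müller glia-like (VEGFA-treated), 7.98% Müller glia-like (NT-treated), 9.11% cone-like (untreated), 11.7% cone-like (VEGFA-treated), 15.9% cone-like (NT-treated), 17.6% rod-like (untreated) and 32.97% rod-like (NT-treated), and shares of all cells with a VEGFA UMI were 3.50% (NT-treated), and the cause was not tested. With median-of-ratios size factors, the VEGFA ratio of VEGFA-treated over untreated was -1.36 (all cells) and -1.28 (Müller glia-like), and the cause was not tested. With every cell weighted the same, the VEGFA ratio of VEGFA-treated over NT-treated was 0.16 (all cells) and -0.28 (Müller glia-like), and that of VEGFA-treated over untreated was -1.15 (all cells) and -1.30 (Müller glia-like). With that equal weight, that of NT-treated over untreated was -1.13 (weighted) and -2.01 (horizontal-like), and genes apart were untreated 19 (rod-like), and the cause was not tested. With genes centred within each library, the VEGFA ratio of VEGFA-treated over untreated was -1.30 (weighted), and genes apart were VEGFA-treated 60 (rod-like). With that centring, class shares were 16.1% cone-like (untreated), 20.6% cone-like (VEGFA-treated), 26.6% cone-like (NT-treated) and 14.98% rod-like (VEGFA-treated), and the cause was not tested. At Leiden resolution 0.5, the VEGFA ratio of VEGFA-treated over untreated was -1.31 (weighted), and genes apart were untreated 8 (rod-like) and VEGFA-treated 8 (rod-like). At the coarser resolution, class shares were 16.1% cone-like (untreated), 23.01% cone-like (VEGFA-treated), 25.7% cone-like (NT-treated), 17.6% rod-like (untreated), 10.2% rod-like (VEGFA-treated) and 31.6% rod-like (NT-treated), and gene ratios of opposite sign were -0.98 (GDF15, NT-treated over untreated) in rod-like cells, and the cause was not tested. At Leiden resolution 2, the VEGFA ratio of VEGFA-treated over NT-treated was -0.28 (weighted), -0.92 (Müller glia-like), -0.45 (cone-like) and -0.58 (horizontal-like), and that of VEGFA-treated over untreated was -1.75 (Müller glia-like) and -0.84 (cone-like). At the finer resolution, that of NT-treated over untreated was -2.10 (horizontal-like), and genes apart were VEGFA-treated 29 (Müller glia-like). At the finer resolution, class shares were 9.12% Müller glia-like (untreated), 12.1% Müller glia-like (VEGFA-treated), 11.3% cone-like (untreated), 13.2% cone-like (VEGFA-treated) and 18.5% cone-like (NT-treated), and gene ratios of opposite sign were 1.36 (COL1A1, VEGFA-treated over untreated) and -0.13 (IFI27, NT-treated over untreated) in Müller glia-like cells, and the cause was not tested.

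With no CPM minimum and at least 20 UMIs, which tests more genes of low counts, genes apart were untreated 1164 (Müller glia-like), 608 (cone-like) and 627 (rod-like) and VEGFA-treated 942 (Müller glia-like), 492 (cone-like) and 742 (rod-like). With 5 CPM added, which draws ratios of low genes toward 0, genes apart were untreated 22 (rod-like) and VEGFA-treated 5 (cone-like) and 20 (rod-like). At a 1.5-fold threshold, a lower bar, genes apart were untreated 395 (Müller glia-like), 66 (cone-like) and 140 (rod-like) and VEGFA-treated 232 (Müller glia-like), 68 (cone-like) and 325 (rod-like). Thinned to 500 UMIs, a lower depth, shares of all cells with a VEGFA UMI were 3.88% (untreated), 1.68% (VEGFA-treated) and 1.65% (NT-treated), and a second random draw gave 4.21%, 2.22% and 1.66%. Unthinned, at full depth, shares of all cells with a VEGFA UMI were 34.3% (untreated), 31.5% (VEGFA-treated) and 28.5% (NT-treated). Without clusters 9, 20 and 24, the VEGFA ratio of VEGFA-treated over NT-treated was -0.29 (weighted), -0.78 (Müller glia-like) and -0.49 (cone-like), and that of NT-treated over untreated was -0.64 (Müller glia-like). Without these 3 clusters, genes apart were untreated 19 (cone-like) and 10 (rod-like) and VEGFA-treated 6 (rod-like), and the p53 target median VEGFA-treated over NT-treated was 0.25 (weighted). Without these 3 clusters, gene ratios of opposite sign were -1.29 (GDF15, NT-treated over untreated), -0.03 (PPP1R27, VEGFA-treated over untreated) and -0.13 (PPP1R27, NT-treated over untreated) in rod-like cells, and the cause was not tested. With clusters at a common share within each class, the VEGFA ratio of VEGFA-treated over NT-treated was -0.69 (Müller glia-like) and 0.28 (rod-like), and that of VEGFA-treated over untreated was -1.29 (Müller glia-like) and -0.85 (cone-like). With that common share, that of NT-treated over untreated was -0.59 (Müller glia-like) and -0.43 (rod-like), since clusters of a class differ in VEGFA and in size between libraries. Without cluster 15, the gene ratio of opposite sign was 0.20 (NRXN3, VEGFA-treated over untreated) in cone-like cells, with few cells of that cluster in the treated libraries. Without cluster 0, with fewer untreated cells in the total, class shares were 14.9% Müller glia-like (untreated), 21.1% cone-like (untreated) and 26.99% rod-like (untreated). Under the looser naming rule, the VEGFA ratio of VEGFA-treated over untreated was -1.08 (weighted), -1.06 (Müller glia-like) and -2.19 (horizontal-like), and that of NT-treated over untreated was -0.83 (weighted), -0.65 (Müller glia-like) and -1.47 (horizontal-like). Under that naming rule, class shares were 41.9% Müller glia-like (untreated), and the cause was not tested.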

Other observations

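KRT19 and GFAP are named here because their values were seen to stand out. Reactive gliosis genes, induced in glia after injury, had a median log2 ratio of VEGFA-treated to NT-treated of 0.41 in Müller glia-like cells (percentile 100), with 6 of 15 members at least 2-fold higher and 1 lower. Among them were LCN2 at 1.29, 471 and 0.116 CPM, with 1 UMI in the NT-treated library and a ratio of 11.98 (9.50 to 17.29), S100A11 at 44.8, 389.7 and 19.9 CPM, ANXA1 at 7.59, 50.1 and 5.24 CPM and S100A6 at 31.8, 95.01 and 14.6 CPM. Markers of epithelium lay beside them, as with KRT19 at 1.71, 166 and 0.116 CPM (1 UMI in the NT-treated library, ratio of VEGFA-treated to NT-treated 10.48 (8.0 to 15.78)), and GFAP, a glial filament, stood at 16.8, 11.5 and 0.582 CPM (ratio 4.31 (3.06 to 5.95)), with 90% of its UMIs in 16, 13 and 3 cells. In the same class of the VEGFA-treated library 8 cells held 90% of the S100A9 UMIs and 10 those of KRT13, genes typical of surface epithelia. Whether such cells also carried the gliosis genes was not tested, so the gliosis median is not read as a response of the glia. Immediate early genes, which respond within minutes to stimulation or dissociation, had a median of -0.48 in Müller glia-like cells (percentile 0), with 0 of 13 members at least 2-fold higher and 0 lower, and EGR1 at 557, 349 and 618 CPM and EGR2 at 61.3, 53.9 and 95.1 CPM. In bipolar-like cells their median was 0.28 (percentile 98.5), with 2 of 9 higher, FOS at 40, 38.7 and 13.2 CPM and EGR1 at 46.8, 23.9 and 11.1 CPM. Phototransduction genes in Müller glia-like cells had a median of -0.44, or -0.08 with the mitochondrial limit at 10%, with 3 of 11 members at least 2-fold lower in the VEGFA-treated library, such as GNAT1 at 13.6, 9.88 and 35.6 CPM.

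Receptors and relatives of VEGFA were measured over all kept cells. FLT1, a VEGF receptor, stood at 92.2, 60.2 and 52.4 CPM, KDR, the main signalling receptor of endothelium, at 21.4, 14.5 and 9.35 CPM, NRP1 at 17.98, 6.74 and 4.45 CPM, NRP2 at 10.5, 9.21 and 8.77 CPM, VEGFB at 37.9, 41.8 and 38.8 CPM and PGF at 16.6, 11.02 and 10.2 CPM. In Müller glia-like cells FLT1 at 419.7, 321 and 498 CPM and NRP1 at 49.01, 28.1 and 15.8 CPM had log2 ratios of VEGFA-treated to NT-treated of -0.63 (-0.69 to -0.57) and 0.83 (0.55 to 1.11). Weighted to 1 class composition, the medians of VEGFA-treated over NT-treated were 0.50 for cell cycle arrest genes (percentile 100), -0.28 for outer segment genes (percentile 0.12), -0.22 for photoreceptor transcription factors (percentile 2.48; -0.10 and -0.03 for these lists without clusters 9, 20 and 24) and -0.15 for ribbon synapse genes (percentile 9.03). Metallothioneins, which bind zinc and copper, had weighted medians to untreated of 0.20 for VEGFA-treated and 0.49 for NT-treated (percentiles 89.4 and 100), and Müller glia function genes 0.20 and 0.40 (percentiles 89.9 and 100). Ribosomal protein genes stood at -0.03 and -0.14 and cholesterol synthesis genes at 0.04 and 0.00.

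Clusters 10 and 19, unnamed and led by OPN1SW, the pigment of blue cones, had median doublet scores of 0.107 and 0.109 against 0.0640 over all kept cells, and cluster 0 had 0.115. Depth went opposite ways, with median UMIs of 21168 and 41792.5 in clusters 10 and 19 and 2698 in cluster 0. Relative to the median of a cell's own library these were 2.065, 3.485 and 0.365. What these clusters are was not tested.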
